A study of Homo sapiens with 24 samples.

How the data were processed

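ATAC-seq libraries of G401 cells were made with an Active Motif kit, per the labels' protocols, from cells under selection with 1 ug/ml puromycin. The submitters' processing notes name Trim Galore 0.4.4 (read trimming), BWA (alignment), SAMtools 1.2, bedtools 2.24.0 and MACS2 2.1.1.20160309 (peak calling), and the build GRCh37, also called hg19. The BWA version and the settings of each step are not given in the sources used here, nor whether reads were shifted for the transposase. Peaks were deposited as 1 list per library, so replicates were not pooled. Each deposited list gives, for every peak, its position, its summit, a fold enrichment (a linear ratio of pileup over local background) and the -log10 of its p-value and of its q-value. The lowest -log10 q lay between 1.30 and 1.31 in all lists. The shortest peak was 64 or 65 bp in the libraries without a compound and 80 or 81 bp in the others, and the cause of this difference was not tested.

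Groups and replicate numbers were taken from the labels, 3 libraries in each of 8 groups. For 1 library, shDCAF5 with DMSO replicate 3, the file name and the labels differ, and the labels were followed. A further 6 lists that belong to no sample of the series were not used here. No statement in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No pair of lists was a duplicate: within groups the Jaccard index of called sites was 0.561 to 0.725.

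Scores of peaks in different lists are not on one scale, so they served only to rank, filter or describe peaks within their own list, and libraries were compared by whether a peak was called. Chromosomes 1 to 22, X and Y were used. Peaks of all lists of 1 experiment that shared at least 1 base were merged into sites, which gave 304263 sites without a compound, 216404 in the DMSO and BRM014 experiment and 277021 in the dTAG experiment. A site was called in a library when a peak of its list overlapped it. It was gained when called in 3 of 3 treated and 0 of 3 control libraries, and lost in the opposite case. Balanced sites were called in 1 of 3 or in 2 of 3 libraries of both genotypes without a compound. When a library without a compound was left out, the same numbers of calls were required of fewer libraries. This skewed the balanced set to the genotype of that library. Coordinates are 1-based on hg19.

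Tests were exact permutation tests over all relabellings (20 for 3 against 3, 400 over 2 strata), exact stratified tests per site with Benjamini-Hochberg adjustment, Fisher's exact tests on site lists, and, for interactions, 100000 permutations of residuals of the additive fit. All were two-sided except the similarity test, which counts splits with as large a difference. The count of labelled splits for the V-1 odds ratio also takes only the direction seen. The tests, the site definition, most alternatives and the rule for named sites were fixed before the data were examined. The rule takes, per contrast, the 5 gained and 5 lost sites with the lowest median rank by -log10 q as a share of the list, and for shDCAF5 takes them among sites changed in both experiments.

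Depth was not recorded and was recovered from the lists. Fold enrichment and -log10 p together were solved for the summit pileup and the local background. Where this left a choice of solutions, the one nearer a whole number was taken, which favours whole numbers. Peaks with a -log10 p under 250, at least 95.6% of every list, were solved. The pileup was a whole number of reads (within 0.05) for 99.99% of solved peaks in the lowest list. The most frequent background is that of the whole genome and scales with depth. It ranged from 0.31 to 1.49 reads. For depth-matched lists, added after seeing the data, pileups were thinned at random to the shallowest library of the experiment, and peaks kept where they passed the highest of the lists' p-value limits. Deeper libraries call more weak sites, so a site absent from a list was not detected at that depth rather than closed.

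The code was tested on simulated data drawn from the sites without a compound. The pileup solver was right for 100% of simulated peaks. Of 200 simulated changed sites among 304263, 73.5% were called gained, together with 1691 unchanged sites. The stratified test called 0% of 200 changed sites, as too few sites changed for any adjusted p to pass, and 53.8% of 3000. Changed sites were given a fixed high rate of calls in treated libraries and a fixed low rate in control libraries. The shares called gained, 73.5% and 53.8%, follow from these rates, so they test the code and do not measure sensitivity in the real data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

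Alternatives were a stricter peak threshold (-log10 q of at least 5), equal-length lists, peaks that cover most of a site, sites from windows of 100 bp on each side of summits, at least 2 of 3 libraries, a replicate block, 3 strata, shares minus balanced sites, each library left out in turn, and, added later, depth matching, the logit scale and matching on rank. No genome or annotation of build hg19 was used here, so promoter shares, motif shares and gene lists planned for named genes were not analysed here and sites carry no gene names. Peak lists hold no expression values, so neither the knockdown nor the degradation of DCAF5 was checked.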

Results

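Chromatin accessibility was measured by ATAC-seq, which marks open DNA by the insertion of a transposase, in G401, a cell line from a human malignant rhabdoid tumour. Such tumours lack SMARCB1, a core subunit of the SWI/SNF chromatin remodelling complexes. The 24 libraries fell into 8 groups of 3. A control hairpin (shCTRL) or a hairpin against DCAF5 (shDCAF5), a substrate receptor of CUL4-DDB1 ubiquitin ligases, was compared in cells without a compound. The same hairpins were compared in a separate experiment with DMSO, the solvent, or with 1 uM BRM014, an inhibitor of the ATPase subunits of SWI/SNF. In a dTAG line, whose tagged DCAF5 is degraded when V-1 is added, 500 nM V-1 for 4 h was compared with DMSO.

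The lists held 195695 ± 16627 peaks (SD, n = 3) with shCTRL and 199059 ± 11671 with shDCAF5 without a compound. In the DMSO and BRM014 experiment they held 112045 ± 7707 (shCTRL, DMSO), 93913 ± 10456 (shCTRL, BRM014), 131395 ± 12515 (shDCAF5, DMSO) and 108090 ± 7018 (shDCAF5, BRM014). The dTAG lists held 182878 ± 22326 peaks with DMSO and 167446 ± 32473 with V-1. The genomic background pileup, which scales with depth, averaged 1.23 ± 0.136 and 1.22 ± 0.183 reads for shCTRL and shDCAF5 without a compound, with single libraries from 1.09 to 1.43. It was lower in the DMSO experiment, at 0.425 ± 0.0458 for shCTRL and 0.577 ± 0.158 for shDCAF5. V-1 replicate 1 was shallow, with a background of 0.516 reads and 130324 peaks against 190584 and 181431 in the other V-1 libraries.

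The comparison of shDCAF5 with shCTRL asked which sites open or close when DCAF5 is lowered. Without a compound, 11795 sites were gained, meaning called in all 3 shDCAF5 libraries and in none of 3 shCTRL libraries, and 5589 were lost. With DMSO, 9069 sites were gained and 1583 lost. Of all 304263 sites, 119446 were called in all 6 libraries without a compound. Of the 32641 sites called in exactly 3 of these 6 libraries, 36.1% were gained and 17.1% lost, where chance gives 5% each way. With DMSO these shares were 44.2% and 7.72%.

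More sites changed in the same direction in both experiments, which share no library, than independent lists would give, although most did not repeat. Of the sites gained without a compound 14.7% were also gained with DMSO, and of those lost 2.899% were also lost. Only 2285 of the gained sites were called in all 3 shDCAF5 libraries with DMSO, whose lists were shorter, and 1737 of these were gained again. Of the lost sites 456 were called in all 3 shCTRL libraries with DMSO, and 162 of these were lost again. Most changed sites therefore could not repeat under the 3 of 3 rule. In both experiments, 1737 sites were gained, against 330 for independent lists (odds ratio 7.29), and 162 were lost, against 25.9 (odds ratio 7.10, Fisher's exact test, two-sided p = 1.14e-75). Only 1 site was gained without a compound and lost with DMSO, and 12 went the other way. In the exact stratified test per site, two-sided, 3040 sites could be tested, and the same 1737 gained and 162 lost sites passed at a Benjamini-Hochberg adjusted p of 0.00800. They are the same by construction, since no other pattern of calls can pass this test. Each of these was called in 6 of 6 libraries of one genotype and 0 of 6 of the other, which chance would give for 7.60 sites each way. With the BRM014 libraries added as a further stratum, the test called 272 gained and 53 lost sites. Neighbouring sites are not independent, and sites called in all 6 libraries can be neither gained nor lost, which alone favours an overlap. The odds ratios and their p therefore describe the site lists only. For gained sites the odds ratio was 3.796 when 2 of 3 libraries sufficed and 5.63 with equal-length lists, where 818 sites were gained in both. For lost sites it was 3.47 when 2 of 3 libraries sufficed, 2.74 with equal-length lists and 4.44 without shCTRL replicate 1 of the experiment without a compound.

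Among sites gained in both experiments, the best ranked in their lists lay on chromosome 1 at 215768700 to 215768826, on chromosome 8 at 109132492 to 109132874, on chromosome 4 at 80786526 to 80786765 and at 99351897 to 99352158, and on chromosome 11 at 19529716 to 19529957 (hg19). The fold enrichment the authors' caller gave the chromosome 1 site was between 21.5 and 24.8 in the 6 shDCAF5 lists without a compound and with DMSO. That of the site at 99351897 on chromosome 4 was 18.2 to 34.4, with a median rank at 22.5% of the list from the top. All 5 were also called in 3 of 3 shDCAF5 libraries with BRM014 and in 0 of 3 shCTRL libraries with BRM014. The sites at 109132492 on chromosome 8 and at 80786526 and 99351897 on chromosome 4 were called in all 6 dTAG libraries, whether V-1 was added or not. The best-ranked sites lost in both lay on chromosome 16 at 3206704 to 3206850, chromosome 1 at 90283386 to 90283903, chromosome 9 at 131007274 to 131007433, chromosome 5 at 149698612 to 149698909 and chromosome 3 at 37477201 to 37477377. The chromosome 1 site had a fold enrichment of 4.85 to 6.21 in the shCTRL lists without a compound and with DMSO. With BRM014, 4 of these 5 lost sites were again called in 3 of 3 shCTRL and 0 of 3 shDCAF5 libraries, while the chromosome 5 site was called in neither.

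Both gained and lost sites were weaker than shared ones. This follows in part from the definition, since a gained or lost site had to be missed by all lists of a genotype. The median within-list rank, counted from the top, was at 65.1% of the list for gained and 73.0% for lost sites without a compound, against 31.9% for sites called in all 6 libraries. It was 49.5% for sites gained and 63.8% for sites lost in both experiments, which also had to be called in the shorter DMSO lists. The median width of sites gained in both was 198 bp, and that of sites lost in both 149 bp.

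The number of peaks itself did not differ past the threshold: shDCAF5 minus shCTRL was 11357 peaks over both experiments (exact permutation test within experiments, two-sided p = 0.155). The difference was 13722 (exact permutation p = 0.0350) when only peaks with a -log10 q of at least 5 were kept. Leaving out shCTRL replicate 2 without a compound gave 15655 (exact permutation p = 0.0400), and depth-matched lists gave 7249 (exact permutation p = 0.16). With DMSO alone the difference was 19350, and 9722 in depth-matched lists (exact permutation p = 0.1 each). With lists shortened to equal length the DMSO experiment gave 4500 gained and 2197 lost sites, so part of its surplus of gained sites went with list length. Without a compound, equal-length lists gave 11115 gained and 6108 lost. Counts rise when fewer libraries have to hold a site, and the surplus of gained sites without a compound was smallest without shCTRL replicate 1, at 13425 gained and 11674 lost. Lost sites there numbered 9191 without shCTRL replicate 3 and 8935 without shDCAF5 replicate 1. With DMSO they numbered 3351, 2496 and 3145 without shCTRL replicates 1, 2 and 3 and 3170 without shDCAF5 replicate 1, and 13936 sites were gained without shDCAF5 replicate 3. Sites lost in both experiments numbered 245 without shDCAF5 replicate 1 of the experiment without a compound, and 265 and 264 without shCTRL replicates 1 and 3 with DMSO. Every 3 against 3 comparison has 10 splits and cannot give a p below 0.10.

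**Figure D1:**
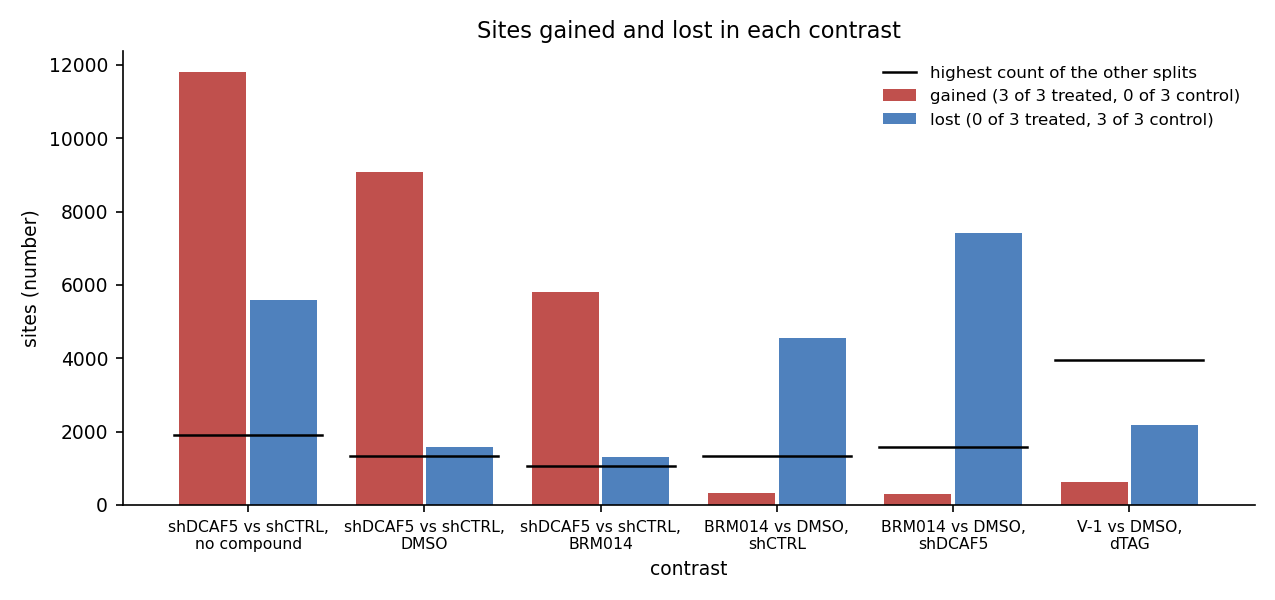
Bars give the number of sites gained (red) and lost (blue) in each contrast, and black lines the highest count, in one direction, that other splits of the same 6 libraries gave. The shDCAF5 bars lean to gained sites (11795 against 5589 without a compound), the BRM014 bars to lost sites (4547 and 7414), and both V-1 bars lie under the line at 3958.

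BRM014 mainly removed sites in both genotypes. In shCTRL cells 4547 sites were lost and 323 gained with the inhibitor, and in shDCAF5 cells 7414 were lost and 288 gained. The sites lost in shCTRL and in shDCAF5 cells overlapped at 583 sites, against 156 for independent lists, and 4 sites moved in opposite directions. Both lists hold only sites called in every DMSO library of their genotype, which alone favours an overlap, so no test of it is given.

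The best-ranked sites lost with BRM014 in shCTRL cells lay on chromosome 6 at 52382419 to 52382682, chromosome 3 at 123469627 to 123469887 and at 112950740 to 112950986, chromosome 20 at 62497203 to 62497350 and chromosome 12 at 6396055 to 6396308. All 5 were still called in 3 of 3 shDCAF5 libraries with BRM014. In shDCAF5 cells the best-ranked lost sites lay on chromosome 2 at 122547955 to 122548154, chromosome 20 at 45375704 to 45375913, chromosome 11 at 64683527 to 64683707 and at 59554539 to 59554756, and chromosome 1 at 186206110 to 186206363. The chromosome 2 site, with a fold enrichment of 24.1 to 31.8 in the shDCAF5 DMSO lists, was called in 0 of 3 shCTRL DMSO libraries. All 5 were called in 0 of 3 BRM014 libraries of either genotype. The best-ranked of the few sites gained in shCTRL were on chromosome 5 at 132445067 to 132445158, chromosome 3 at 127147601 to 127147776, chromosome 15 at 93374003 to 93374107, chromosome 17 at 74033767 to 74033989 and chromosome 1 at 27864911 to 27865079. Those gained in shDCAF5 were on chromosome 11 at 57408605 to 57408710, chromosome 7 at 26222953 to 26223144, chromosome 1 at 110731630 to 110731793, chromosome 8 at 42185733 to 42186017 and chromosome 12 at 52577497 to 52577660. Their median ranks were at 42.6% to 54.8% of their lists, below the named lost sites at 16.9% to 22.5%.

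The number of peaks fell by 18132 with BRM014 in shCTRL and fell by 23305 in shDCAF5 (exact permutation test, two-sided p = 0.1 each). With equal-length lists 2127 sites were lost and 828 gained in shCTRL, and 3292 were lost and 1084 gained in shDCAF5. Leaving out any of the 6 libraries raised the few gained sites over 1.5 times, to between 544 and 1400 in shCTRL, highest without shCTRL BRM014 replicate 3, and to between 456 and 1188 in shDCAF5, highest without shDCAF5 BRM014 replicate 2. Lost sites in shCTRL numbered 7840 and 7565 without DMSO replicates 1 and 3 and 7398 without BRM014 replicate 2, and in shDCAF5 11444 and 12285 without DMSO replicates 2 and 3.

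Under BRM014, shDCAF5 against shCTRL gave 5797 gained and 1306 lost sites, which became 3413 and 2114 with equal-length lists. Gained sites numbered 9057 and 8787 without shDCAF5 replicates 2 and 3, and lost sites 2316, 2072 and 3613 without shCTRL replicates 1, 2 and 3 and 2286 without shDCAF5 replicate 1. The best-ranked gained sites were on chromosome 1 at 199530871 to 199530952 and at 69052328 to 69052408, chromosome 8 at 20017050 to 20017130, chromosome 14 at 69529120 to 69529201 and chromosome 5 at 126522410 to 126522766. The first 4 were 81 or 82 bp wide, at the 81 bp minimum of these lists, with fold enrichments from 32.5 to 82.6, and none was called in any of the 6 libraries without a compound. The fifth was called in 3 of 3 libraries of every hairpin group except shCTRL with BRM014. The best-ranked lost sites were on chromosome 22 at 24964306 to 24964476, chromosome 7 at 75934819 to 75935114, chromosome 15 at 67081502 to 67081654, chromosome 2 at 44531915 to 44532104 and chromosome 1 at 90283409 to 90283911. The last of these overlaps a site lost in both experiments above.

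Whether sites opened with shDCAF5 depended on the SWI/SNF ATPase was followed in a set fixed in other libraries, the 11795 sites gained without a compound. A peak lay over 32.1% ± 5.67 (SD, n = 3) of them in shDCAF5 libraries with DMSO and over 9.07% ± 1.21 with BRM014. In shCTRL libraries these shares were 4.17% ± 0.903 and 1.14% ± 0.371. The share was 17.9 percentage points higher with shDCAF5 than with shCTRL over both treatments (exact permutation test within treatments, two-sided p = 0.005, the smallest possible). With BRM014 it fell by 13.0 points over both genotypes (exact permutation test within genotypes, two-sided p = 0.005). The change with BRM014 in shDCAF5 minus that in shCTRL, the interaction, was -20.0 points (permutation of residuals, two-sided p = 0.00184, an estimate at the floor of 0.00216 that the possible assignments allow). With equal-length lists the effect of shDCAF5 was 8.61 points, that of BRM014 -5.33 and the interaction -8.74, each again at the smallest p of its permutation test. In proportion the falls were alike, 71.8% in shDCAF5 and 72.8% in shCTRL, and on the logit scale the interaction was -0.198 (permutation p = 0.448), so the difference holds on the scale of percentages only. Minus the share of balanced sites, which were called equally often in both genotypes and follow list length, the BRM014 effect was -19.4 points in shDCAF5 (exact permutation p = 0.1) and 0.203 in shCTRL (exact permutation p = 1). Balanced sites went from 10.9% with DMSO to 7.65% with BRM014 in shCTRL, and from 13.5% to 9.91% in shDCAF5. In both genotypes they fell less in proportion than gained sites, so the 0.203 points do not show that BRM014 had no effect on gained sites in shCTRL. Pooled, the BRM014 effect minus balanced sites was -9.60 (exact permutation p = 0.055). It was -4.20, -3.53 and -4.13 without shDCAF5 replicates 1, 2 and 3 of the experiment without a compound, where the balanced set was skewed to shDCAF5. It passed at -9.96 without shCTRL DMSO replicate 2 (exact permutation p = 0.0350), at -10.2 without shCTRL BRM014 replicate 3 (exact permutation p = 0.02) and at -7.03 with equal-length lists (exact permutation p = 0.005).

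The 5589 sites lost without a compound behaved differently. They were called at 20.1% ± 2.32 in shCTRL and 10.7% ± 3.25 in shDCAF5 with DMSO, and at 16.3% ± 4.55 and 9.26% ± 2.097 with BRM014. The share was lower with shDCAF5 by -8.27 points (exact permutation test, two-sided p = 0.01), and by -5.37 without shCTRL replicate 1 of the experiment without a compound. The difference between BRM014 and DMSO was -2.61 points (exact permutation p = 0.195), and -1.40 and -1.67 without shCTRL BRM014 replicate 3 and shDCAF5 DMSO replicate 1. With equal-length lists its sign turned and it passed, at 2.86 points (exact permutation p = 0.005), so the direction depends on how list length is treated.

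Because weak sites drop out of any shorter list, sites of equal rank were compared, a choice made after the shares were seen. Of the sites gained without a compound, 2285 were called in all 3 shDCAF5 libraries with DMSO. These were called at 34.5% ± 3.82 (SD, n = 3) in the BRM014 libraries of the same genotype. Sites called in all 6 libraries without a compound and matched on rank reached 73.7% ± 4.90, a difference of -39.2 ± 1.77 points that was between -37.2 and -40.4 in every library. In shCTRL cells, 456 sites lost with shDCAF5 and held by all DMSO libraries were called with BRM014 at 67.4% ± 9.36, against 67.1% ± 8.61 for rank-matched sites.

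**Figure D2:**
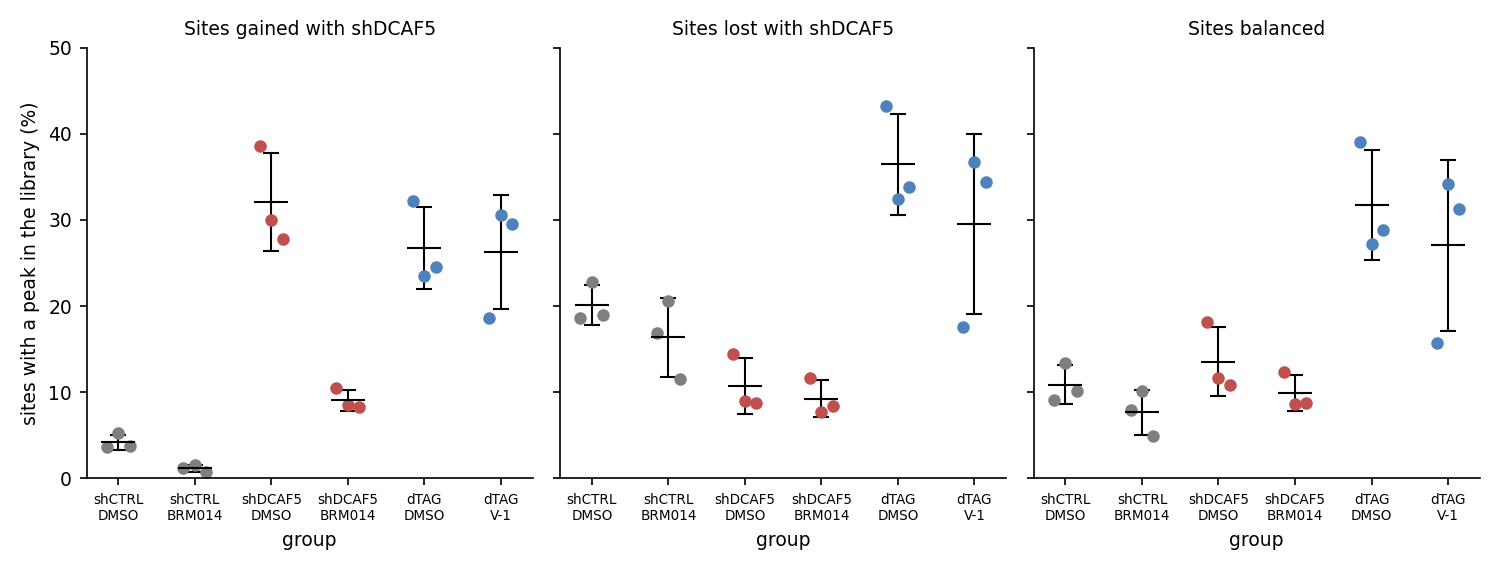
Points are the percentage of sites gained, lost or balanced without a compound that had a peak in each library of the other experiments, by group, with mean and SD (n = 3). Gained sites are called at 27.8% to 38.5% in shDCAF5 with DMSO and at 8.22% to 10.5% with BRM014, while V-1 replicate 1 lies lowest of the dTAG libraries in all panels.

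**Figure D3:**
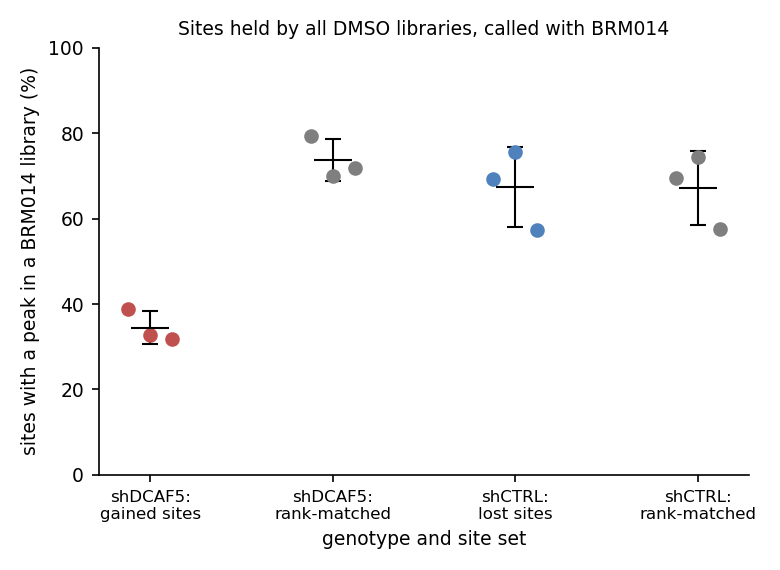
Points are the percentage of sites, held by all 3 DMSO libraries of a genotype, that had a peak in each BRM014 library of that genotype, with mean and SD (n = 3). Sites gained with shDCAF5 lie at 31.7% to 38.8%, below the rank-matched sites at 70.0% to 79.2%, and sites lost with shDCAF5 lie with their rank-matched sites in shCTRL.

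The dTAG line asked what 4 h of DCAF5 loss does to accessibility. With V-1, 624 sites were gained and 2192 lost, and other splits of the same 6 libraries gave up to 3958 in one direction. Lists of one group were hardly more alike than lists of different groups (within minus between Jaccard index 0.00355, exact p = 0.3), where the shDCAF5 contrast without a compound gave 0.0850 (exact p = 0.1, the smallest possible). The V-1 index was 0.0104 with equal-length and 0.00716 with depth-matched lists, above that of every other split (exact p = 0.1 each), but 0.00410 without V-1 replicate 1 (exact p = 0.5) and 0.00470 with depth matching and without that library (exact p = 0.4). Leaving out DMSO replicates 1, 2 and 3 turned it to -0.0149, -0.00925 and -0.00878, and it was 0.0285 and 0.0220 without V-1 replicates 2 and 3. Of the sites of this experiment, 5226 were gained and 3081 lost with shDCAF5 without a compound, and V-1 changed few of these. Among the sites that both changed, 31 were gained with both and 46 lost with both. A further 6 were gained with V-1 and lost with shDCAF5, and 28 the opposite (odds ratio 8.49, Fisher's exact test, two-sided p = 5.55e-06, sites not independent). The odds ratio describes only these few sites. With 0.5 added to each count the odds ratio was 7.91, the highest of 20 labelled splits of the dTAG libraries, of which the next gave 3.39. This count takes only the direction seen. The odds ratio was not recomputed with depth matching or without V-1 replicate 1, and the test was chosen after the counts were seen. The 11795 shDCAF5-gained sites were called at 26.7% ± 4.75 with DMSO and 26.3% ± 6.60 with V-1, a difference of -0.483 points (exact permutation test, two-sided p = 1). Minus balanced sites, the shares were -4.98 ± 1.65 and -0.782 ± 3.38, a difference of 4.20 points (exact permutation p = 0.1). The 5589 shDCAF5-lost sites were called at 36.5% ± 5.88 with DMSO and 29.6% ± 10.5 with V-1, a difference of -6.93 points (exact permutation p = 0.6) that was -0.913 without V-1 replicate 1, -3.56 without DMSO replicate 1 and -10.5 without V-1 replicate 2. Minus balanced sites it was -2.24 (exact permutation p = 0.1). It was -0.0269, 0.184 and 0.0391 without shCTRL replicates 1, 2 and 3 of the experiment without a compound, where the balanced set was skewed to shCTRL.

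The best-ranked sites gained with V-1 were on chromosome 21 at 48119754 to 48119916, chromosome 1 at 44444780 to 44444927 and at 158082442 to 158082582, chromosome 20 at 30556342 to 30556444 and chromosome 12 at 54749266 to 54749384. The chromosome 21 site had a fold enrichment of 22.4 to 49.3 and was also called in 2 of 3 libraries of both groups without a compound. The best-ranked lost sites were on chromosome 2 at 34704321 to 34704414, chromosome 15 at 54904141 to 54904221, chromosome 5 at 55598833 to 55598913, chromosome X at 137438879 to 137438961 and chromosome 8 at 91566344 to 91566425. The last 4 were 81 to 83 bp wide and were called in none of the libraries without a compound. Without the shallow V-1 replicate 1, 4221 sites were gained and 2529 lost, and the difference for shDCAF5-gained sites was 3.31 points (exact permutation p = 0.4), and 2.25 without DMSO replicate 1 (exact permutation p = 0.7). Minus balanced sites it was 2.32 without V-1 replicate 1 (exact permutation p = 0.2). Equal-length lists gave 932 gained and 1305 lost sites, and depth-matched lists 861 and 1813. Without DMSO replicates 1, 2 and 3 in turn, gained sites numbered 1878, 974 and 1036 and lost sites 3488, 6123 and 5786. Without V-1 replicates 2 and 3 these were 1386 and 1660, and 5873 and 4481.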

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

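Chosen only after the result was seen were the thinning to equal depth, the logit scale, the weighing of the share of gained sites that repeated, the direction of V-1 sites, the weighing of V-1 without replicate 1, the counts of splits for single contrasts and the rank-matched comparison, although the bound for the last was set before its values were seen.

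The fall of shDCAF5-gained sites with BRM014 differed between genotypes, with an interaction of -20.0 percentage points, and of -19.6 points after subtracting balanced sites (permutation of residuals, p = 0.00184 for each). The latter was -9.16 with equal-length lists. It was -11.5 and -13.0 without shDCAF5 replicates 2 and 3 of the experiment without a compound, where the balanced set was skewed to shDCAF5. On the logit scale the permutation test of the interaction gave p = 0.448, so a share near 0 in shCTRL that cannot fall as far may account for the difference between genotypes. Shallower libraries do not account for the whole fall within shDCAF5, which was -23.0 points as reported and between -18.6 and -19.0 points in depth-matched lists over 10 random thinnings. The background of these libraries was similar, at 0.577 ± 0.158 reads with DMSO and 0.545 ± 0.133 with BRM014 (SD, n = 3). Thinning also takes weak sites out of the DMSO lists, and the effect of shDCAF5 shrank with it from 17.9 to 14.1. Whether depth carries part of the fall is therefore not shown. Weak sites dropping from shorter lists are argued against as the whole cause, since gained sites differed from rank-matched sites by -39.2 ± 1.77 points (SD, n = 3). Equal-length lists brought the BRM014 effect over both genotypes from -13.0 to -5.33. That cut also takes weak sites out of the DMSO lists, and the effect of shDCAF5 shrank with it from 17.9 to 8.61. It therefore cannot tell whether list length carries part of the fall. A larger dependence on the SWI/SNF ATPase at sites opened with shDCAF5 stays open as a hypothesis.

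For sites lost with shDCAF5, minus balanced sites, the interaction was 2.75 points (permutation of residuals, p = 0.0217). It was -1.85 points with equal-length lists (permutation p = 0.00184), so its direction depends on list length. Without shCTRL replicates 1, 2 and 3 of the experiment without a compound it was 1.2004, 1.62 and 1.28 (permutation p = 0.430, 0.312 and 0.381), and without the shDCAF5 replicates 6.39, 6.17 and 6.41. In these settings the balanced set was skewed to the genotype with fewer libraries, so the values do not show the weight of single libraries alone. The interaction also missed the threshold without shCTRL DMSO replicates 1 and 2 (2.64 and 2.66), shDCAF5 DMSO replicate 1 (2.33) and shDCAF5 BRM014 replicate 3 (2.62), and was 1.71 without shCTRL BRM014 replicate 3. No finding is drawn from it.

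The surplus of gained over lost sites with shDCAF5 was weighed against depth, since shDCAF5 libraries with DMSO were deeper. Depth matching lowered the number of gained per lost sites in that experiment from 5.73 to between 3.18 and 3.31 over the thinnings, and equal-length lists gave 4500 gained and 2197 lost, so depth may carry part of the surplus but is argued against as its whole cause; without a compound, depth-matched lists gave 12034 and 5487. A difference of culture or handling within 1 experiment cannot be told apart for most gained sites. Of those gained without a compound 14.7% were also gained with DMSO, above independent lists but a minority. That share could not decide the question, because only 2285 of these sites were called in all 3 shDCAF5 libraries with DMSO. Of the 2285, 1737 were gained again. An effect of the hairpin or the transduced cells other than the loss of DCAF5 cannot be told apart from that loss either, because 1 hairpin label was used. The direction of the V-1 sites followed shDCAF5 with an odds ratio of 8.49, or 7.91 with 0.5 added to each count. This was the highest of 20 labelled splits (next 3.39). Each split is counted there in both directions, so 10 are distinct and a two-sided share cannot fall below 0.1. Chance therefore stays open there. Depth stays open too, since the odds ratio was not recomputed with depth matching or without the shallow V-1 replicate 1. That library held 17.5% of shDCAF5-lost and 18.7% of shDCAF5-gained sites. The other V-1 libraries held 34.4% to 36.7% and 29.5% to 30.6%.

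The V-1 shift of shDCAF5-gained sites against balanced sites was 4.20 points. Without the shallow V-1 replicate 1 it was 2.32 points, so that library may carry part of the shift but not its sign. Whether the rest lies beyond chance cannot be settled with 3 libraries against 2.

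Other splits of the same libraries were counted for the numbers of gained plus lost sites. For sites changed in the same direction in both experiments, 1 of 100 splits drawn within experiments, the real one, reached 1899, and the highest other gave 32. This argues against a chance assignment of these libraries to the genotypes. It cannot exclude chance differences between cultures, since the replicates may be technical. Each single contrast has 10 splits, too few for a share under 0.05. The real counts and the highest others were 17384 and 2182 for shDCAF5 without a compound, 10652 and 1495 with DMSO, 7103 and 1192 with BRM014, 4870 and 1509 for BRM014 in shCTRL, 7702 and 1733 in shDCAF5, and 2816 and 4061 for V-1. For V-1, 3 of the 10 splits gave as many sites.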

How the results depend on the processing

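Depth limits what a missing peak means. List length moved counts, shares and some directions: with equal-length lists the shares of shDCAF5-gained sites gave 8.61 points for shDCAF5, -5.33 for BRM014 and -8.74 for the interaction, in place of 17.9, -13.0 and -20.0. The settings that thin to equal depth, take logits or match ranks were added after seeing the data, and for changed values the cause was not tested unless stated. Other widths of promoters, motif windows and gene neighbourhoods were not run, since no hg19 annotation was used here.

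Requiring only 2 of 3 libraries raises every count by construction: gained and lost sites were then 22757 and 17536 for shDCAF5 without a compound, 19297 and 5799 with DMSO, 13512 and 5378 with BRM014, 2295 and 12486 for BRM014 in shCTRL, 2417 and 17681 in shDCAF5, 5993 and 10953 for V-1, and 3714 and 832 in both experiments. Equal-length lists gave 4500 gained with DMSO, 3413 gained and 2114 lost with BRM014, 828 and 2127 for BRM014 in shCTRL, 1084 and 3292 in shDCAF5, 1305 lost with V-1, and 818 gained in both experiments, also by the stratified test. Summit windows gave 471 sites gained with BRM014 in shDCAF5, against 288. A -log10 q of at least 5 gave 323 sites gained with V-1, 105 lost in both experiments, also by the stratified test, and a genotype effect of 13722 peaks (exact permutation p = 0.0350). With 3 strata the test called 272 gained and 53 lost sites.

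The V-1 effect on shDCAF5-gained sites turned from -0.483 to 2.86 points with equal-length lists, 1.16 with depth matching, 3.23 with depth matching and no V-1 replicate 1, and 4.20 minus balanced sites (exact permutation p from 0.1 to 0.7). Depth matching without that library turned the V-1 peak difference to 1871 and gave 3973 gained sites. The BRM014 effect on gained sites was -9.60 minus balanced sites, and the interaction -0.198 on the logit scale. For lost sites the BRM014 effect, -2.61, turned to 2.86 with equal-length lists (exact permutation p = 0.005) and 0.834 minus balanced sites. The interaction, 2.35, became -1.44 (permutation p = 0.00184) and 2.75 (permutation p = 0.0217). Minus balanced sites it turned to -1.85 with equal-length lists (permutation p = 0.00184).

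Same-numbered libraries deviated from their group means with correlations of -0.0162 to 0.0274 and 17 of 48 tests had the own number as best match, so they share only a number. With a replicate block the BRM014 effect on lost sites, -2.61 points, passed (permutation p = 0.0313), and no other call changed.

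Leaving out 1 library in turn gave these ranges. Peak differences were -4635 to 11960 for shDCAF5 without a compound, -27000 to 3130 for V-1 and 7358 to 15655 for genotype over both experiments. Lost sites were 7002 to 11674 without a compound, 1974 to 3351 with DMSO and 1696 to 3613 with BRM014. Gained sites were 10512 to 13936 with DMSO and 6547 to 9057 with BRM014. For BRM014 they were 544 to 1400 gained and 5394 to 7840 lost in shCTRL, and 456 to 1188 and 8841 to 12285 in shDCAF5, and for V-1 974 to 4221 and 2529 to 6123. Sites lost in both experiments were 176 to 265. The V-1 difference in similarity was -0.0149 to 0.0285, its effect on gained sites -2.66 to 3.31, that on lost sites minus balanced sites -2.91 to 0.184, and the interaction for lost sites -0.0537 to 4.47. Fewer libraries to satisfy raise counts by construction. Values minus balanced sites also move with the skew of the balanced set when a library without a compound is left out.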

Other observations

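The values here were chosen after the data were seen. Sites gained with shDCAF5 were unevenly spread over chromosomes 1 to 22 and X, the only ones compared. The share of the sites of the experiment without a compound that were gained was lowest on chromosome 19 in both experiments, at 3.07% without a compound and 1.55% with DMSO, and highest on chromosome 18 without a compound (4.62%) and on chromosome 13 with DMSO (3.59%). Lost sites made up the largest share on chromosome 17 without a compound (2.42%) and on chromosome 19 with DMSO (0.635%), and on chromosome 19 there were 0.629 and 0.410 lost sites per gained site. On chromosome 18 these ratios were 0.361 and 0.136. No test was run on these shares.

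Sites gained in both experiments lay closer together than balanced sites: 7.60% had another such site within 10000 bp, against 3.998% on average and at most 6.16% in 1000 random draws of as many balanced sites. The balanced sites were neither matched on rank nor required to be called with DMSO. The draws therefore do not show clustering beyond that of equally strong sites. The densest window of 100000 bp was on chromosome 6 from 4300001 to 4400000, where 4 of 14 sites were gained in both experiments and none was lost in both. Windows with 3 such sites lay on chromosome 2 from 19700001 and from 84600001, on chromosome 6 from 130900001 and on chromosome 7 from 22300001. All sites gained without a compound were less clustered than balanced sites, at 19.1% against 23.4%, while those lost were more clustered, at 18.3% against 12.1%. Sites lost in both experiments, at 2.47%, lay within the random draws, which reached 3.70%.

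Sites under 100 bp wide with a fold enrichment over 20 numbered 74 in the DMSO and BRM014 experiment, and 65 of them were called in all 12 libraries. Of the rest, 7 were gained with shDCAF5 under DMSO, 8 under BRM014 and 0 lost in either contrast. Without a compound there were 37 such sites, of which 0 were gained and 1 was lost with shDCAF5. The 4 named ones were called in 0 of 6 libraries without a compound, in 3 of 3 dTAG libraries with DMSO and in 2 or 3 of 3 with V-1.

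Over all 24 lists, 47831 of 401751 merged sites were called in every library.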
